A study of Solanum lycopersicum with 8 samples.

How the data were processed

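The series holds 8 RNA-seq libraries of dissected tomato shoot apical meristem, from WT and the late termination (ltm) mutant with 4 and 6 leaves, 2 per group, grouped by the sample titles. The table's columns were matched to samples through the sample descriptions. The labels speak of repeats and do not say whether these were separate pools of plants, so p-values measure only the spread between these libraries, which may be technical. The labels do not give the locus of the mutation, so the mutated gene was not checked in the libraries.

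Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3 were used; the genome build is not given in the sources used here. The deposited signal values are gene counts that the authors divided by a size factor per library. Every value in a library was a whole multiple of the value of 1 read (100% of values, tolerance 1e-06 of the read number), so the whole reads behind the values were recovered. The size factors lay between 0.883 and 1.09. The intervals and floors given for genes with 3 reads or fewer in a group come from these reads (exact binomial, Clopper-Pearson, 95%; floor of 3 reads over the group), and they cover counting error only.

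The design fixed before the data were examined had foreseen counts with edgeR's quasi-likelihood test, or limma if the values were normalized. The values were normalized, so limma 3.58.1 (R 4.3.3, trend) was fitted to log2(value + 1) for all 8 libraries with a mean per group, on the 19186 of 34722 genes with a value of at least 10 in at least 2 libraries. The fold changes therefore understate the change of low genes. The 5 comparisons were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives.

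On simulated data with the real means and library sizes, for WT 6 leaves against WT 4 leaves with 18987 genes in the step and 50 genes per fold size, limma called 58% of genes changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. Among its 193 calls 15 were false. The changed genes were drawn from those with a mean value of at least 50, so the shares do not cover lower genes. The adjusted threshold also becomes stricter when fewer genes change. An absence of calls in the real data therefore does not rule out changes of these sizes. Of 1000 lists of 12 unchanged genes, 5.7% had at least 1 call adjusted over the list alone, for ltm 4 leaves against WT 4 leaves. The simulation held no structure shared between libraries.

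The replicate letters were checked for pairing. The correlation across genes of the A libraries' deviations from their group means was 0.52 between WT and ltm at 4 leaves, 0.39 between WT and ltm at 6 leaves, 0.37 between the WT stages, 0.24 and 0.21 across genotype and stage, and 0.13 between the ltm stages. All 6 were above 0.1, so the letters were taken to pair the libraries, a hint from the data and not from the labels, and the letter as a block was fitted as an alternative.

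The 5 gene lists below were fixed by identifier before the data were examined: floral transition, floral organ, meristem maintenance, organ boundary and lateral organ. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), adjusted over 20 tests. A further 18 lists were compiled after the table was seen and before its values were examined, and 13 of them were tested, adjusted over 65 tests. Lists by annotation words were also planned and not used, because the table pairs its identifiers with no annotation text. The pairing of symbols with identifiers was set down from general knowledge of tomato genes. It was compared with NCBI RefSeq gene names (assembly SLM_r2.1): of the 43 fixed pairs, 38 matched a RefSeq symbol or synonym, all 38 on the same chromosome and 37 in the same order. The 5 unmatched ones were TMF, STM3, BL, PHAN and GLO1, whose names rest on the identifier alone. The one out of order was Solyc05g056620, which had been listed as MACROCALYX. Its name is uncertain, so it is given by its identifier. Of 196 further pairs, 96 matched, unevenly over the lists. The clock pairs were all unmatched, as were most of the SBP-box, heat-shock and trichome pairs. The unmatched names rest on the identifier alone.

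Genes were named by a rule fixed in advance: called genes with an annotated function, list members past the threshold (up to 4 per list), and any tested member of the floral transition list. With 1 gene called over all genes at most, counts adjusted over a list alone lead the text; that reading was chosen after the values were seen. Some genes were named outside the rule. These include SFT, AN, J2 and LIN, which were below the filter, and WUS and CLV3, which did not pass. They also include IAA7, AGL6, FYFL and MBP3, which come from the further lists. For Solyc01g100600 and Solyc05g050590 the reason is given where they are named. The planned slope over genes called in WT could not be given because 0 were called. The slope over all tested genes, which the design had not named, stands in its place.

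Alternatives tried were DESeq2, limma-voom and edgeR with RLE, upper quartile or TMM scaling on the recovered reads, TMM or upper quartile rescaled values, no filter, a filter of 5 CPM, pseudocounts of 0.1 and 5, a fold threshold, the replicate block, only the 4 libraries of a comparison, and leaving out each library in turn. With 1 library left in a group, that library was assumed to vary like those of the other groups. The floral transition list was also set against each WT 6 leaves library alone, beside random lists of as many genes of similar mean expression.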

Results

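RNA of the shoot apical meristem, the dome of dividing cells that forms the leaves and later the flowers of the shoot, was sequenced from wild-type tomato and from the late termination (ltm) mutant. Meristems were dissected from acetone-fixed seedlings with 4 leaves and with 6 leaves, and each of the 4 combinations of genotype and stage was represented by 2 libraries, labelled A and B. The deposited table listed 34722 genes. The number of reads assigned to genes lay between 17895357 in WT 6 leaves B and 21987881 in WT 4 leaves A, and between 22008 and 22622 genes per library had at least 1 read. The 10 most abundant genes took 3.04% to 3.91% of the reads of a library. Values below are normalized read counts, given as mean ± SD of 2 libraries, and fold changes are on the log2(value + 1) scale with their standard error.

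The B libraries at 4 leaves stood apart from the other libraries in both genotypes. On the first principal component, which held 35.4% of the variance, WT 4 leaves B lay at 46.4 and ltm 4 leaves B at 44.2, while the remaining 6 libraries lay between -38.9 and 5.57. On the second, with 20.8% of the variance, WT 6 leaves B was highest at 49.4. The light-harvesting list holds genes of the chlorophyll-binding proteins of green tissue, and also RBCS2 and PSBO, which encode other photosynthesis proteins. At 4 leaves its median B to A difference was 0.32 (log2) in WT and 0.95 in ltm. The heat-shock genes had one of 1.55 in WT and 1.13 in ltm, and the flavonoid genes one of 0.95 in WT and 1.29 in ltm. Trichome genes were at 0.49 and 0.33, and SBP-box genes at -0.32 and -0.64. Meristem maintenance genes were at -0.38 and -0.43.

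**Figure D1:**
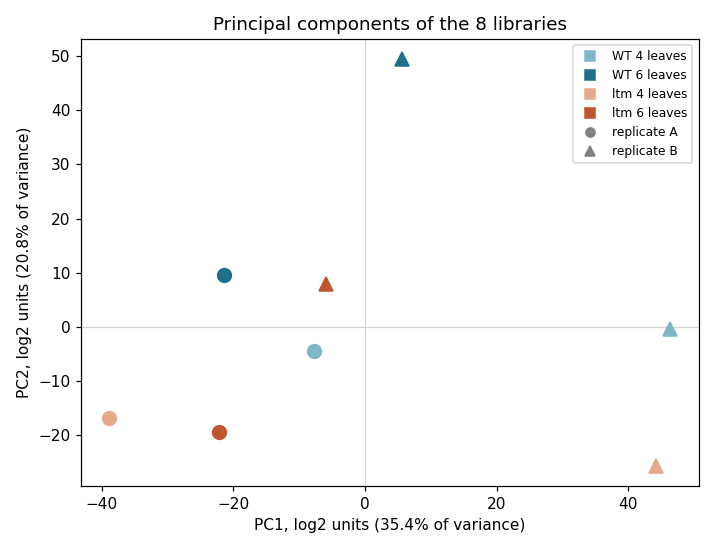
Scores of the 8 libraries on the first and second principal components of log2(value + 1) over 19186 genes, in log2 units, with color for the group and symbol for the replicate letter. The B libraries of WT and ltm at 4 leaves sit at 46.4 and 44.2 on the first component, apart from the other 6.

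The comparison of WT meristems at 6 and 4 leaves addresses the change from vegetative growth to the floral transition that the series' design names. The sample titles give leaf numbers, and the descriptions of the A libraries read Young at 4 leaves and mid at 6 leaves. The stage of the meristems was not tested. Genes of the floral transition list, fixed before the data were examined, were higher at 6 leaves. The FRUITFULL-like MADS-box genes were among them. MBP20 rose from 8.94 ± 3.60 to 90.2 ± 26.2 (log2 fold change 3.22 ± 0.57 SE, adjusted p = 0.00255 over the list alone), FUL1 from 43.4 ± 11 to 138.0 ± 5.05 (1.67 ± 0.34, adjusted p = 0.00305) and FUL2 from 113.2 ± 12.7 to 292.7 ± 134 (1.29 ± 0.34, adjusted p = 0.0110). Solyc05g056620, a gene of uncertain name that was listed as a MADS-box gene, had 1 read in the WT 4 leaves libraries together and 254 in the WT 6 leaves libraries, a ratio of 276 with a 95% counting interval of 49.1 to 10951. STM3, listed as a relative of the flowering integrator SOC1, rose by 0.79 ± 0.15 and BLIND (BL), a MYB gene needed for lateral meristems, by 0.47 ± 0.13, each in limma. The call of FUL2 was lost without WT 6 leaves B (0.81 to 1.77 over the libraries left out in turn), and that of BL without WT 4 leaves B or WT 6 leaves B (0.35 to 0.60).

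Of the 18 genes on the floral transition list, 11 passed the filter on low values. Adjusted over the list alone, 7 of these were higher in WT at 6 leaves and 0 lower, and adjusted over all genes tested, 0 passed in limma and 3 in DESeq2 (Solyc05g056620, MBP20 and STM3). The seventh was COMPOUND INFLORESCENCE (S), a WUSCHEL-type homeobox gene, at 39.6 ± 7.30 and 120.5 ± 85.9 (1.38 ± 0.53), whose value in WT 6 leaves B was 181 and in WT 6 leaves A 59.7. Its call was lost in 11 of 22 alternatives, including without WT 4 leaves A, WT 4 leaves B, WT 6 leaves B, ltm 6 leaves A or ltm 6 leaves B, with log2 fold changes of 0.59 to 2.18 over the libraries left out in turn. With the replicate letter as a block S no longer passed (adjusted p = 0.0522 over the list alone), which left 6 genes. The flower meristem gene FALSIFLORA (FA) stood at 4880 ± 9.58 and 5249 ± 223 and JOINTLESS (J) at 3336 ± 655 and 3862 ± 516, without passing. The list as a set was higher (camera adjusted p = 2.25e-09), and the adjusted p was 0.139 with an estimated correlation. Without WT 6 leaves B, 4 of the list genes passed. Of the lists compiled after the table was seen, the flavonoid genes had lower values at 6 leaves in 13 of 13 tested members (median -0.56, camera adjusted p = 0.00306, adjusted p = 0.698 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. They were high in WT 4 leaves B, and without both 4 leaves B libraries the list no longer passed in WT (median -0.30). The median of the ltm stage change then went from -0.27 to 0.27, and that of the difference between the stage changes from 0.22 to 0.46. The flavonoid result thus depended on these libraries, and 1 library per genotype is left at 4 leaves without them. The florigen gene SFT had 0 reads in every library except WT 6 leaves B, where its value was 10.2. Flower organ identity genes stayed near 0: 7 of the 8 on that list fell under the filter. The tested one, the B-class gene TM6, rose from 596.9 ± 127 to 883.9 ± 13.6 (0.58 ± 0.23, unadjusted p = 0.0341 in limma). Its list held 1 tested gene, so its call carries no adjustment. Adjusted over all genes its p in limma was 0.727. The call of TM6 was lost without WT 4 leaves B, WT 6 leaves A or WT 6 leaves B, with log2 fold changes of 0.36 to 0.80 over the 8 libraries left out in turn.

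Over all 19186 genes tested with limma, 0 differed between WT at 6 and 4 leaves after adjustment, while 1158 had an unadjusted p under 0.05. edgeR on the recovered reads called 0 genes and DESeq2 10, of which 7 were higher at 6 leaves.

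**Figure D2:**
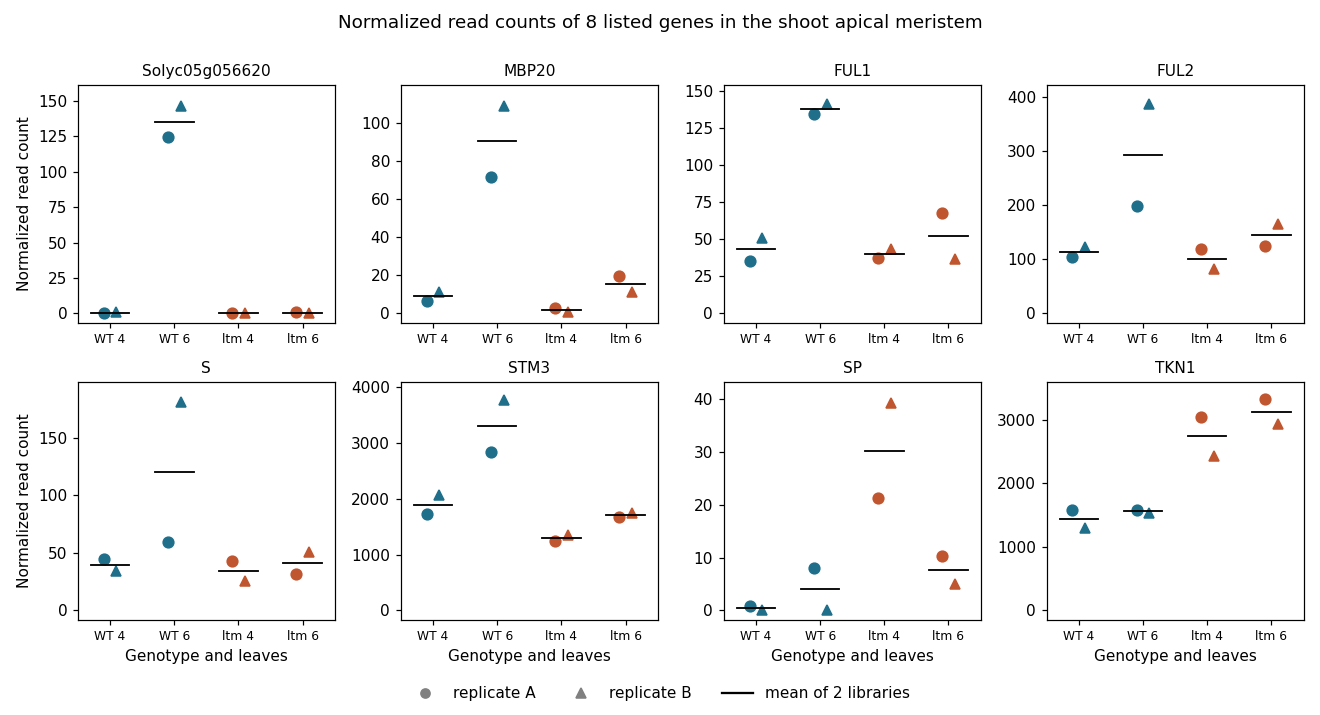
Normalized read counts, on linear axes, of 8 genes of the floral transition and meristem lists in each of the 8 libraries; circles are replicate A, triangles replicate B, and bars the mean of 2 libraries. Solyc05g056620 was at 124.5 and 146.1 in the WT 6 leaves libraries and at most 1.04 in the other 6, and TKN1 was at 2424 or more in each ltm library and at 1583 or less in each WT library.

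The mutant was compared with the wild type at 6 leaves. Floral transition genes were lower in ltm: Solyc05g056620 had 1 read in the ltm 6 leaves libraries against 254 in WT, a ratio of 277 with a 95% counting interval of 49.2 to 10978. MBP20 was at 15.4 ± 6.28 in ltm against 90.2 ± 26.2 in WT (-2.50 ± 0.57, adjusted p = 0.00744 over the list alone), FUL1 at 52.6 ± 22.0 against 138.0 ± 5.05 (-1.44 ± 0.34, adjusted p = 0.00744) and STM3 at 1712 ± 42.3 against 3307 ± 662 (-0.94 ± 0.15, adjusted p = 0.00157). FUL2, S and FA were also lower, with log2 fold changes of -0.95 ± 0.34, -1.36 ± 0.53 and -0.44 ± 0.17. TERMINATING FLOWER (TMF), whose loss makes the first inflorescence flower early, was higher, at 4244 ± 238 against 3247 ± 244 (0.39 ± 0.14). The calls of FUL2 and S were lost without WT 4 leaves A, WT 4 leaves B, WT 6 leaves B, ltm 6 leaves A or ltm 6 leaves B, with log2 fold changes of -1.43 to -0.46 for FUL2 and -2.15 to -0.57 for S over the libraries left out in turn. Those of FA (-0.56 to -0.33) and TMF (0.31 to 0.46) were lost without any 1 of these libraries or WT 6 leaves A, and those of MBP20 (-2.90 to -2.10) and FUL1 (-1.87 to -1.01) without WT 6 leaves B or ltm 6 leaves B. Adjusted over the list alone, 7 of the 11 tested genes were lower and 1 higher. Over all genes tested 0 passed in limma and 3 in DESeq2 (STM3, Solyc05g056620 and MBP20). As a set the list was lower (camera adjusted p = 2.11e-05), with an adjusted p of 0.161 with an estimated correlation. The number of floral transition genes past the threshold fell to 1 without WT 6 leaves B, to 2 without ltm 6 leaves B and to 4 without ltm 6 leaves A, WT 4 leaves A or WT 4 leaves B. Without both 4 leaves B libraries it was 8.

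Outside that list, TKN1, a KNOX homeobox gene of the meristem, was higher in ltm at 6 leaves, at 3124 ± 276 against 1556 ± 33.9 (1.0 ± 0.15, adjusted p = 9.6e-04 over the list alone), and none of the other 6 genes of the meristem list, which include WUS and CLV3, passed. GOBLET (GOB), a NAC gene of organ boundaries, was at 5019 ± 95.6 against 3683 ± 346 (0.45 ± 0.13, adjusted p = 0.0391 over the list alone) and was the 1 of 5 boundary genes past the threshold. Its call was lost without any 1 of the 4 libraries at 6 leaves, with log2 fold changes of 0.35 to 0.55 over the libraries left out in turn. GOB lies within a run of 5 neighbouring tested genes with a mean genotype statistic of 6.59. LANCEOLATE (LA), a TCP gene of leaf development, was lower, at 511.3 ± 46.0 against 764.0 ± 126 (-0.57 ± 0.14, adjusted p = 0.0211 over the list alone), the 1 of 5 lateral organ genes past it; the call was lost without WT 6 leaves B or ltm 6 leaves A, with log2 fold changes of -0.74 to -0.40 over the libraries left out. Over all genes tested none of these 3 lists had a call in limma, and DESeq2 called 1 gene, TKN1. The lateral organ list was lower as a set (camera adjusted p = 0.0236), with an adjusted p of 0.259 with an estimated correlation and of 0.0514 without both 4 leaves B libraries. Trichome genes, a list compiled after the table was seen, had lower values in ltm in 7 of 8 tested members (camera adjusted p = 0.0279, adjusted p = 0.613 with an estimated correlation and 0.0714 without both 4 leaves B libraries), with 0 members past the threshold adjusted over the list alone.

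Over all genes, limma called 1 gene between ltm and WT at 6 leaves, and 1237 had an unadjusted p under 0.05. The called gene, Solyc01g100600, was at 14898 ± 187 in ltm and 1932 ± 125 in WT (2.95 ± 0.15, adjusted p = 7.2e-04), higher in both ltm libraries. It has no annotation in the tables used here and was named because it was the only one called. edgeR called 1 gene and DESeq2 36, with 23 higher in ltm. The limma count was 2 without WT 4 leaves A or without WT 4 leaves B, and 4 without both 4 leaves B libraries. Solyc05g050590, chosen after its values were seen, was not called by limma (adjusted p = 0.34 at 4 leaves and 0.11 at 6 leaves) or edgeR and was called by DESeq2 at both stages (adjusted p = 0.0352 and 0.00267); it had 458 reads in the WT 6 leaves libraries and 0 in the ltm 6 leaves libraries, at least 166-fold lower in ltm when 3 reads over the group are taken as the floor. Against WT 6 leaves A alone the bound was 113-fold and against B alone 227-fold.

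At 4 leaves SELF PRUNING (SP), a repressor of flowering of the florigen family, was higher in ltm. It had 1 read in the WT libraries together and 60 in the ltm libraries, a ratio of 62.2 with a 95% counting interval of 10.8 to 2499 (adjusted p = 0.0340 over the list alone). STM3 was lower, at 1302 ± 78.4 against 1894 ± 240 (-0.54 ± 0.15, adjusted p = 0.0448), with log2 fold changes of -0.67 to -0.41 over the libraries left out in turn. These were the 2 of 11 floral transition genes past the threshold adjusted over the list alone, and 0 passed over all genes. The count was 0 without WT 4 leaves B, ltm 4 leaves B, ltm 6 leaves A or ltm 6 leaves B, and 0 without both 4 leaves B libraries; the call of STM3 was also lost without ltm 4 leaves A. ANANTHA (AN), an F-box gene of flower formation, was under the filter, with 0 reads in WT and 15 in ltm, at least 5.19-fold higher against a floor of 3 reads. At 6 leaves AN was higher in ltm too, with 1 read in WT and 9 in ltm (ratio 8.26, 95% counting interval 1.14 to 362). J2 and LIN, list genes also under the filter, were lower in ltm at 6 leaves, with 27 and 16 reads in WT against 1 and 0. At 4 leaves TKN1 was at 2737 ± 442 against 1441 ± 201 (0.92 ± 0.15, adjusted p = 0.00169 over the list alone) and GOB at 4454 ± 429 against 3304 ± 359 (0.43 ± 0.13, adjusted p = 0.0478 over the list alone). The call of GOB was lost in 15 of 23 alternatives, including without WT 4 leaves B, WT 6 leaves A, WT 6 leaves B, ltm 4 leaves A, ltm 6 leaves A or ltm 6 leaves B, with log2 fold changes of 0.32 to 0.54 over the libraries left out in turn. Over all genes DESeq2 called TKN1 of these genes and limma 0. The floral list as a set did not pass (camera adjusted p = 0.117). Among lists compiled after the table was seen, clock genes had higher values in ltm in 13 of 14 tested members (camera adjusted p = 0.00306), and wound and jasmonate genes lower values in 10 of 13 (camera adjusted p = 0.00618). The adjusted p was 0.613 with an estimated correlation for each, and 0 clock genes and 1 wound or jasmonate gene passed adjusted over the list alone. Without both 4 leaves B libraries, 1 library per genotype is left at 4 leaves. The median of the wound and jasmonate list then went from -0.24 to -0.027 and that of the clock list from 0.28 to 0.47. The clock difference thus lay more in the A libraries.

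Solyc01g100600 was again the 1 gene called by limma over all genes, at 12073 ± 2418 in ltm against 1650 ± 113 in WT (2.86 ± 0.15, adjusted p = 9.2e-04), and 558 genes had an unadjusted p under 0.05. edgeR called 1 and DESeq2 16. Solyc05g050590 had 234 reads in WT and 0 in ltm, at least 75.2-fold lower with the same floor. WT 4 leaves B held 198 of these reads, at a value of 206.7 against 32.9 in A, and against WT 4 leaves A alone the bound was 21.7-fold.

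From 4 to 6 leaves in ltm, MBP20 rose from 2.03 ± 1.44 to 15.4 ± 6.28 (2.47 ± 0.57, adjusted p = 0.0264), the 1 floral transition gene past the threshold adjusted over the list alone. With the replicate letter as a block the number was 3, with STM3 (0.40 ± 0.15) and BL (0.42 ± 0.13) added. It was 0 without WT 6 leaves A, WT 6 leaves B, ltm 4 leaves B, ltm 6 leaves A or ltm 6 leaves B. The floral list was higher as a set (camera adjusted p = 2.38e-04), with an adjusted p of 0.161 with an estimated correlation, and so was the boundary list (0.00783), with an adjusted p of 0.375 with an estimated correlation. Over all genes limma called 0, with 612 at an unadjusted p under 0.05. edgeR called 0 and DESeq2 4.

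The difference between the stage changes of the genotypes was tested as an interaction. Solyc05g056620 was the 1 floral transition gene past the threshold adjusted over the list alone (adjusted p = 0.00609), with 1 read at 4 leaves and 254 at 6 leaves in WT and 0 and 1 in ltm. Without WT 6 leaves A or without WT 6 leaves B it fell under the filter on low values and the count was 0, and the count was 2 without ltm 6 leaves A. The floral list had a smaller stage change in ltm as a set (camera adjusted p = 6.21e-05), with an adjusted p of 0.161 with an estimated correlation. Over all genes limma called 0 and 138 had an unadjusted p under 0.05; edgeR and DESeq2 called 0 each.

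Across the 19186 tested genes, the least-squares slope of the ltm stage change on the WT stage change was 0.35, with a correlation across genes of 0.41. Over the 139 genes at an unadjusted p under 0.01 in WT (limma) the slope was 0.41, and over the 11 tested floral transition genes 0.16. The slope over all tested genes was 0.75 without ltm 4 leaves A and -0.039 without ltm 4 leaves B, so 1 library set its sign. The 4 leaves B libraries of WT and ltm stood apart in the same direction. This enters both stage changes and would give a positive slope by itself. The slope therefore cannot tell a stage change shared by the genotypes from a deviation shared by these libraries. Genes are not independent replicates, and no p is given. The mutant difference at 4 leaves and the WT stage change share the WT 4 leaves libraries. As limma called 0 genes for the WT stages, an overlap of calls could not be tested. At an unadjusted p under 0.01, 4 genes passed in both in the same direction, against a mean of 0.52 (range 0 to 3) in 100 simulations of unchanged groups with the same controls and 0.42 for independent lists. The covariance of the fold changes was 0.035, against 0.055 (range 0.050 to 0.062) in these simulations, and the correlation 0.29 against 0.50. The simulations held no structure shared between libraries, whereas the A deviations of WT and ltm at 4 leaves correlated at 0.52. The 2 control libraries are too few to be split.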

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

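The tests of the floral genes and of the 4 leaves B libraries in this part were chosen after the results were seen. The stage change differed between the genotypes for Solyc05g056620, whose interaction on the log2 scale was -6.09; its value in ltm and in WT at 4 leaves rests on 1 read or fewer per group, so the fitted size depends on the pseudocount. The other gene with such a difference was MBP3, a MADS-box gene of the AGAMOUS family on a list compiled after the table was seen, with an interaction of 1.48 (adjusted p = 0.0064 over the list alone, limma): it was at 135.2 ± 15.5 and 66.2 ± 0.727 in WT at 4 and 6 leaves and at 60.7 ± 0.344 and 84.3 ± 9.46 in ltm (n = 2).

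Floral transition genes were lower in ltm than in WT at 6 leaves. A smaller share of meristem tissue in the ltm libraries would lower the meristem genes as well, but their median log2 fold change was 0.0068 (SD 0.49 over 7 genes) against -0.94 for all 11 tested floral genes. The calls rest in part on WT 6 leaves B: without it 1 of the 7 lower genes kept its call, and without WT 6 leaves A 5 did, while Solyc05g056620 fell under the filter in each case. The floral genes were lower against each WT library taken alone, with 9 of the 11 genes lower in each case. The median was -0.46 against WT 6 leaves A alone and -1.14 against B alone. Of 10000 random lists matched on mean expression, 1 and 0 were as low. The random lists ignore that floral genes may vary together, and both medians use the same ltm libraries. The random lists therefore cannot tell how much of the difference comes from the particular libraries. A later floral transition in the mutant may underlie the pattern, and a difference in the exact stage of the dissected WT meristems stays open.

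The 4 leaves B libraries stood apart in both genotypes. A difference in depth is argued against by B over A totals of 0.897 in WT and 1.03 in ltm. More leaf tissue stays open. The lateral organ list had a median B over A of -0.11 (SD 0.11) against 0.51 for the light-harvesting list. Its median value in the 4 leaves A libraries was already 2862, against 1665 for the light-harvesting list, which would hide a small added share. The meristem maintenance list was lower in B than in A at 4 leaves, with medians of -0.38 in WT and -0.43 in ltm. The organ boundary list was at -0.22 and -0.20. At 6 leaves both lists were higher in B. A smaller share of meristem tissue in the 4 leaves B libraries would go with these values, which do not exclude other causes. A shared day or batch stays open too: the deviations of WT and ltm at 4 leaves correlated at 0.52 across genes, but this restates that both B libraries stood apart and would also come from leaf tissue in both, and the labels name no batch.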

How the results depend on the processing

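The counts for the floral transition list and the alternatives with TMM, the DESeq2 block, rescaled values, the 5 lists together, the list without Solyc05g056620 and the libraries that stood apart were chosen after seeing the data; the cause of the changes below was not tested unless stated. DESeq2 called 16, 10, 36 and 4 genes for ltm against WT at 4 leaves, the WT stages, ltm against WT at 6 leaves and the ltm stages, and with the replicate block 26, 15, 92 and 7, against 1, 0, 1 and 0 in limma. With limma the replicate block left these counts and the interaction at 1, 0, 1, 0 and 0. A pseudocount of 5 gave 1 gene for the WT stages and 2 at 6 leaves, no filter 2, the 4 libraries alone 4 at 6 leaves and 0 at 4 leaves, and leaving out both 4 leaves B libraries 4 at 6 leaves. Leaving out 1 library gave 1 to 2 genes at 6 leaves.

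Floral transition genes at 4 leaves (2) ranged from 0 to 3 with 1 library left out, and were 0 with the 5 CPM filter or without both 4 leaves B libraries, and 1 with the fold threshold, the 4 libraries alone or the 5 lists together. For the WT stages (7) they ranged from 4 to 7, with 4 under the 5 CPM filter, which removes low list genes. At 6 leaves (8) they ranged from 1 to 8, with 2 under that filter and 4 with the fold threshold or the 5 lists together. For the ltm stages (1) they ranged from 0 to 1, were 0 with voom, the 5 CPM filter, a pseudocount of 5, the 5 lists together or without both 4 leaves B libraries, 3 with the replicate block, 2 with DESeq2 and the block, and 5 with the 4 libraries alone. For the interaction (1) they ranged from 0 to 2, were 2 with no filter and 0 with DESeq2, its block, edgeR under each scaling, the 5 CPM filter, a pseudocount of 0.1 or the list without Solyc05g056620.

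Of the fixed list tests 6 passed, 0 with an estimated correlation, 6 with the replicate block, 5 without both 4 leaves B libraries and 6 to 10 with a library left out (10 without WT 4 leaves A). The overlap of calls was fixed at 0 in limma by the 0 calls for the WT stages, and was 0 with the 16 and 10 calls of DESeq2. The slope of 0.35 ranged from -0.039 to 0.75 with a library left out. For single listed genes, 455 values under alternatives kept their direction and threshold, 107 kept the direction only and 0 reversed. Rescaling moved the median of all genes by less than 0.01 on the log2 scale. The replicate block ended the call of S for the WT stages, added STM3 and BL for the ltm stages and changed no other call of the fixed lists. Depth limits genes with few reads, such as SP, AN and SFT.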

Other observations

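The further lists were compiled before their values were examined, and the bound on the lowest correlation between neighbours was also set before. The other tests in this part, and the checks without both 4 leaves B libraries, were chosen after the results were seen. Among 13 further lists tested, 11 of 65 tests passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.613); with the replicate letter as a block 17 passed, and without both 4 leaves B libraries 17 passed, of which 6 were among the 11. Beyond the flavonoid, trichome, clock and wound lists in the comparisons above, SBP-box genes had higher values at 6 than at 4 leaves in 13 of 14 members in WT (camera adjusted p = 0.00306) and in ltm (0.0181), trichome genes lower values in 8 of 8 in ltm (0.00306), and clock genes a lower stage change in ltm than in WT in 11 of 14 (0.0407). The SBP-box list was lower and the trichome list higher in the 4 leaves B libraries than in A. Without both of them the SBP-box list passed in WT (median 0.15, adjusted p = 0.0302) and not in ltm (-0.048, adjusted p = 0.609), and the trichome list in ltm did not (adjusted p = 0.154). Of 18 tested auxin response genes of the Aux/IAA family, 2 were lower in ltm at 6 leaves adjusted over the list alone, and 7 of the 18 had a higher value in ltm (camera adjusted p = 0.0391, adjusted p = 0.613 with an estimated correlation). IAA7 was at 190.9 ± 8.41 against 332.1 ± 54.2 in WT (-0.79 ± 0.17, adjusted p = 0.0273 over the list alone, limma, n = 2). The MADS-box gene AGL6 had a value of 0.50 ± 0.707 in ltm and 12.1 ± 1.15 in WT at 6 leaves, and FYFL, a MADS-box gene of the SOC1 branch, was at 45.1 ± 4.44 against 113.9 ± 23.1 (-1.31 ± 0.42, adjusted p = 0.0426 over the list alone, limma). IAA7, AGL6 and FYFL were not rechecked with libraries left out in turn. Light-harvesting genes were lower at 6 than at 4 leaves in both genotypes with the preset correlation: in WT in 19 of 19 members, with a median log2 fold change of -0.36 (camera adjusted p = 0.00104, adjusted p = 0.698 with an estimated correlation), and in ltm with a median of -0.57 (camera adjusted p = 1.18e-10, adjusted p = 0.613 with an estimated correlation), in 18 of 19 members. With the letter as a block 10 of the 19 passed adjusted over the list alone in ltm and 2 in WT, against 0 without it. The difference between the stage changes of the genotypes had a camera adjusted p of 0.0595, of 0.00782 with the block, and an adjusted p of 0.770 with an estimated correlation. Light-harvesting genes were high in the 4 leaves B libraries, and without both of these the medians were -0.18 in WT and -0.21 in ltm. The median difference between the stage changes was then 0.0079, against -0.19 with all libraries.

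The floral genes that rose in WT had, in ltm at 6 leaves, a median log2 fold change of 0.23 (SD 0.31) over WT at 4 leaves, against 1.38 for WT at 6 leaves over WT at 4 leaves. These genes were chosen by their rise from 4 to 6 leaves in WT, so the 1.38 comes from the difference that chose them. A low level in WT at 4 leaves and a high one in WT at 6 leaves both favoured that choice. For these genes, ltm meristems at 6 leaves may stand near the level of WT at 4 leaves. BL did not follow this and stood near the WT 6 leaves level, with a log2 fold change of 0.026 ± 0.13 in ltm against WT at 6 leaves.

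A run of neighbouring genes on chromosome 7 differed together between ltm and WT. Solyc01g100600, with the largest genotype statistic (27.8), was left out of the search, as it weighs heavily in the mean of any run of 5 tested genes that holds it. The strongest run with it had a mean of 8.88, and the other genes of that run had statistics of 2.75 to 5.68. Without it, the strongest run was that from Solyc07g062790 to Solyc07g062850 on chromosome 7, which contains GOB. Its mean genotype statistic was 6.59, against a 95th percentile of 3.96 in 1000 random gene orders and 3.04 for the strongest run by stage. The next run, on chromosome 2, reached 3.99 with 1 gene at 9.94, and the strongest around Solyc01g100600 reached 3.52; the 4 genes that flank it had a mean statistic of 3.61, and 15 of 19134 genes, this one included, had flanks as far from 0. Reads shared between neighbours stay open: in the run with GOB the pairs correlated at 0.67 to 0.945 across the 8 libraries, with the highest just under the bound of 0.95, Solyc01g100600 and Solyc01g100620 correlated at 0.93, and although the lowest pair of the run around them, at 0.47, met the bound set against shared reads, that bound was wrong, since 1 gene that is no copy is enough to meet it. A chromosome segment that differs between the lines may contribute to the run with GOB and, from its flanks, to Solyc01g100600, and effects of the mutation itself on these genes stay open too.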
